A study of Arabidopsis thaliana with 6 samples.

How the data were processed

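RNA of 6 whole-seedling samples of Arabidopsis thaliana at 9 days of age was measured on Affymetrix arrays, 3 of wild type and 3 of the myb3r1 myb3r4 double mutant. Per the labels, seedlings grew on agar medium with sucrose in continuous light, total RNA was extracted with a column kit, and biotin-labelled cRNA was hybridised, 1 array per sample. The labels assign each array to 1 of 3 experimental sets, each with 1 array of each genotype. They do not say whether the sets were separate cultures, so p-values measure only the spread between these samples, which may be technical.

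Per the submitters' processing notes the signals were summarised with MAS5, the Affymetrix algorithm that combines the perfect-match and mismatch probes of a probe set into 1 signal. Its version and scaling target are not given in the sources used here. The deposited values are on a log2 scale: 2 raised to each value was a whole multiple of 1 smallest step in 100% of the values below 3000 steps in every array, with a tolerance of 0.02 step, which shows the base. Taking that step as 0.1 signal unit, the 2% trimmed means were 500.04 to 500.05 and the median signals 185.55 to 217. Each deposited column has a median of 0, so each array was divided by its own median signal before the log, a step that is seen in the values and named in no label. The software for the division and the log is not given in the sources used here. Genes were not centred. MAS5 signals of dim probe sets are noisy on a log scale, and division by the median removes any change shared by most transcripts. A single value, in wild-type replicate 1, equalled the log2 of 1e-10, a stand-in for a signal of 0, and was set to the smallest step of its array. All 6 columns of values were used.

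The table held 22810 probe sets, of which 64 were controls and left out of the tests. Gene names came from the platform annotation given for these probe sets, with symbols and locus tags updated by gene identifier through RefSeq's gene table of assembly GCF_000001735.4 (TAIR10.1). Of the other 22746 probe sets 13513 carried 1 gene, 503 several and 8730 none, and 13436 of those with 1 gene were found in the RefSeq table. Probe sets without a name are unnamed here, not without a gene. Among the tested probe sets 7307 carried 1 gene, 279 several and 6062 none, and of the 72 called 38 carried 1 gene (13 lower, 25 higher) and 31 none. Of 35 genes with several tested probe sets 8 had probe sets of opposite sign, and none of the 35 had a probe set that passed.

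The brightest 60% of probe sets by mean log2 value over all 6 arrays, 13648, were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend; 2 residual and 6.79 prior degrees of freedom), with the experimental set as a block and genotype as the effect. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The pairing comes from the labels, which name the shared set. The deviations of the 2 arrays of a set from their genotype means correlated over probe sets by 0.67, 0.28 and 0.62 in sets 1 to 3. Across sets, wild-type replicate 2 correlated by 0.37 with mutant replicate 3, above its own partner. Mutant replicate 2 correlated by 0.16 with wild-type replicate 3. Arrays of set 1 correlated by -0.61 to -0.28 with arrays of the other genotype in sets 2 and 3. These values part set 1 from the others more than they part set 2 from set 3. SDs are over the 3 arrays of a genotype and SEs are those of the paired fit. On simulated data, 5 draws of 13648 probe sets with 200 changed each, the paired fit recovered 96.4% of 2-fold and 100% of 4-fold changes. It made 12.8 false calls per draw on average. The simulated noise was normal and independent between probe sets, with each spread taken after eBayes had drawn it toward the trend. No 3' bias was simulated, so recovery in these arrays may be lower.

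Gene lists were tested with limma's camera, two-sided, with a preset inter-gene correlation of 0.01, for lists with at least 3 tested members and 1 probe set per gene, the brightest. Probe sets matching several genes were used where all their genes belong to the list. Adjustment was over the 19 lists tested. Camera with an estimated correlation was run beside it, and no list call held after adjustment with it. That form uses only the 2 residual degrees of freedom of the fit, which by itself raises its p-values. The estimates for core histones (0.0019), defence (-0.041) and nuclear genes of chloroplast proteins (-0.035) lay below the preset 0.01. For these 3 lists correlation between genes therefore does not explain the lost call. Limma's rotation test fry, for one direction, gave an adjusted p of 0.0521 for nuclear genes of chloroplast proteins, defence and photosynthesis. For core histones it was 0.0891, and none was under 0.05. The mixed form of fry, which counts changes in either direction, gave adjusted p values of 2.37e-04 for defence and 0.00612 for photosynthesis. For nuclear genes of chloroplast proteins it gave 0.0169 and for core histones 0.0511, and no other list was under 0.05. The first 19 lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. Only 5 of them had enough named members, so 15 lists were added from the names on the array, before the expression of any gene was examined, 14 of which were tested. Lists fixed first with no tested member (targeted genes, other MYB3R genes, mitotic cyclins and CDKB, DNA damage response, heat shock, salicylate and immune response, trichome and epidermal patterning) were not analysed here.

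Genes were named by this rule: the targeted and other MYB3R genes; in each direction the 12 probe sets with exactly 1 gene and the largest difference among those past the threshold and moving the same way in all 3 sets; per list up to 6 members past the threshold over the list alone, with the 2 brightest as examples where fewer than 2 passed; and KN, CYCB1;1, CYCB1;2, CDKB2;1, CDC20.1, EDE1 and HIK. Of a probe set that matches several genes no gene was named. WRKY53 is among the 53 higher probe sets and is named through its list.

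RNA quality was read from control probe sets: the mean 3' minus 5' log2 difference over 6 pairs for GAPDH, actin and ubiquitin genes. It was 1.07, 3.04 and 3.22 in wild type and 1.50, 1.92 and 2.44 in the mutant, replicates 1 to 3. Poly-A control transcripts had median levels of -5.85 and -5.41 in the arrays of set 1 and between -0.92 and -0.84 in those of sets 2 and 3. A 25S ribosomal RNA probe set read 1.87 in mutant replicate 1 and 5.46 to 5.99 in the other 5 arrays.

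Alternatives fixed at the start were the fit without the block, quantile normalization, centring on the array median, no filter on dim probe sets, the brightest 40%, an offset of the 20th percentile (0.115 relative to the array median) before the log, no mean-variance trend, robust empirical Bayes, leaving out each set, an adjusted p of 0.10, a 2-fold minimum, the estimated correlation and the mean of a gene's probe sets. The undone median division and the control difference as a covariate were added after seeing the data. Bootstrap intervals (10000 draws over genes, 95%) treat genes as independent, which they are not. Plots were drawn with matplotlib 3.10.9.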

Results

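Transcript levels were measured in whole seedlings of Arabidopsis thaliana at 9 days of age. The seedlings were either wild type (accession Col-0) or carried mutations in both MYB3R1 and MYB3R4, which encode MYB transcription factors known for acting on genes of mitosis and cytokinesis. Each of 3 experimental sets held 1 wild-type and 1 double-mutant array, which gave 3 arrays per genotype and 6 in all. Levels are log2 signals relative to the median signal of the same array, so a level of 0 is that of a typical probe set. A difference is double mutant minus wild type, fitted with the experimental set as a block. The number of arrays, 3 per genotype, limits the precision of every value.

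The single comparison asked which transcripts differ between myb3r1 myb3r4 and wild-type seedlings. The largest difference was a fall of AT3G02120, annotated as a hydroxyproline-rich glycoprotein family gene, to a dim level, 13.6-fold below wild type as measured. AT3G52110 and AT1G31335 were 4.83-fold and 4.16-fold lower in the mutant, and AT3G02640 and the glycosyl hydrolase genes AT5G55180 and GH9B13 were 3.57-fold, 3.11-fold and 3.07-fold lower. Genes higher in the mutant included the defensin genes PDF1.2, PDF1.2b and PDF1.4, the jasmonate-regulated oxygenase genes JRG21 and AT5G05600, the methionine sulfoxide reductase gene MSRB6 and the transcription factor gene WRKY53. Of 13648 probe sets tested, 72 passed an adjusted p of 0.05 in limma, 19 lower and 53 higher in the mutant, and all 72 moved the same way in all 3 sets. A difference of at least 2-fold was reached by 18 of the lower and 43 of the higher probe sets. At an unadjusted p under 0.05 there were 2374 probe sets, 657 lower and 1717 higher.

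The count depended on the fit. Without the experimental set as a block 1 probe set passed, without a filter on dim probe sets 14 passed, and without set 1, set 2 or set 3 the counts were 1107, 107 and 207. With the division of each array by its median undone, an alternative chosen after seeing the data, 33 probe sets were lower and 41 higher in place of 19 and 53, a share of 44.6% lower in place of 26.4%, and the median difference of all tested probe sets moved by -0.124, from 0.058 to -0.066. Relative to the median of all tested probe sets, the medians of the called lists below are 0.65 (jasmonate and defensins), 0.30 (defence), 0.18 (core histones), 0.11 (nuclear genes of chloroplast proteins), -0.12 (plastid-encoded genes), -0.20 (kinesins) and -0.68 (cold, drought and ABA response).

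Among the genes lower in the mutant, AT3G02120 had a level of 1.34 ± 0.33 (SD, n = 3) in wild type and -2.43 ± 0.29 (SD, n = 3) in the mutant, a log2 difference of -3.77 (SE 0.19, adjusted p = 1.68e-04). Its differences in the 3 sets were -3.65, -3.98 and -3.68. The mutant level is the lowest of all tested probe sets and detection calls were not used here, so the size of this fall is uncertain; with an offset before the log it was 8.79-fold (-3.14). AT3G52110 differed by -2.27 (SE 0.28, adjusted p = 0.0181) and AT1G31335 by -2.06 (SE 0.24, adjusted p = 0.0144). AT3G02640 fell from 2.11 ± 0.29 to 0.27 ± 0.18 (SD, n = 3 each, adjusted p = 0.00784). The brighter genes AT5G55180 and GH9B13 fell to levels 3.11-fold and 3.07-fold below wild type, GH9B13 from 2.74 ± 0.15 to 1.12 ± 0.16 (SD, n = 3 each, adjusted p = 0.00784). SP1L2, a relative of the microtubule-associated SPIRAL1, fell by 1.37 on the log2 scale, and the subtilase gene AT4G20430 fell by 1.33. AT3G51720, AT2G17850, AT5G16250 and ICL, which encodes isocitrate lyase of the glyoxylate cycle, fell by 1.46, 1.22, 1.17 and 1.18. The probe sets 253480_at and 253417_at, unnamed here, fell by 2.25 and 1.98 (adjusted p = 0.00596 and 0.0149).

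Among the genes higher in the mutant, AT3G28220 rose by 1.96 on the log2 scale (SE 0.19, adjusted p = 0.00784) from a wild-type level of 0.14 ± 1.38 (SD, n = 3), a spread between sets that the paired fit removes. MSRB6 rose by 1.84, with differences of 1.94, 1.89 and 1.70 in the 3 sets (adjusted p = 0.00256), and JRG21 rose by 1.59, with differences of 1.61, 1.55 and 1.61 (adjusted p = 0.00696). AT1G57630, a gene with a TIR domain, a module common in plant immune receptors, rose by 1.93 (SE 0.27, adjusted p = 0.0294). AT5G05600, an oxygenase gene of jasmonate catabolism, and AT1G06620, which encodes a related oxygenase, rose by 1.46 and 1.44. AT1G72060 rose by 1.37 and AT3G23550, a transporter gene of the MATE family, by 1.32. CML41, which encodes a calmodulin-like protein, rose by 1.18 (SE 0.17). The unnamed probe set 252265_at rose by 2.01 (adjusted p = 0.00222).

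**Figure D1:**
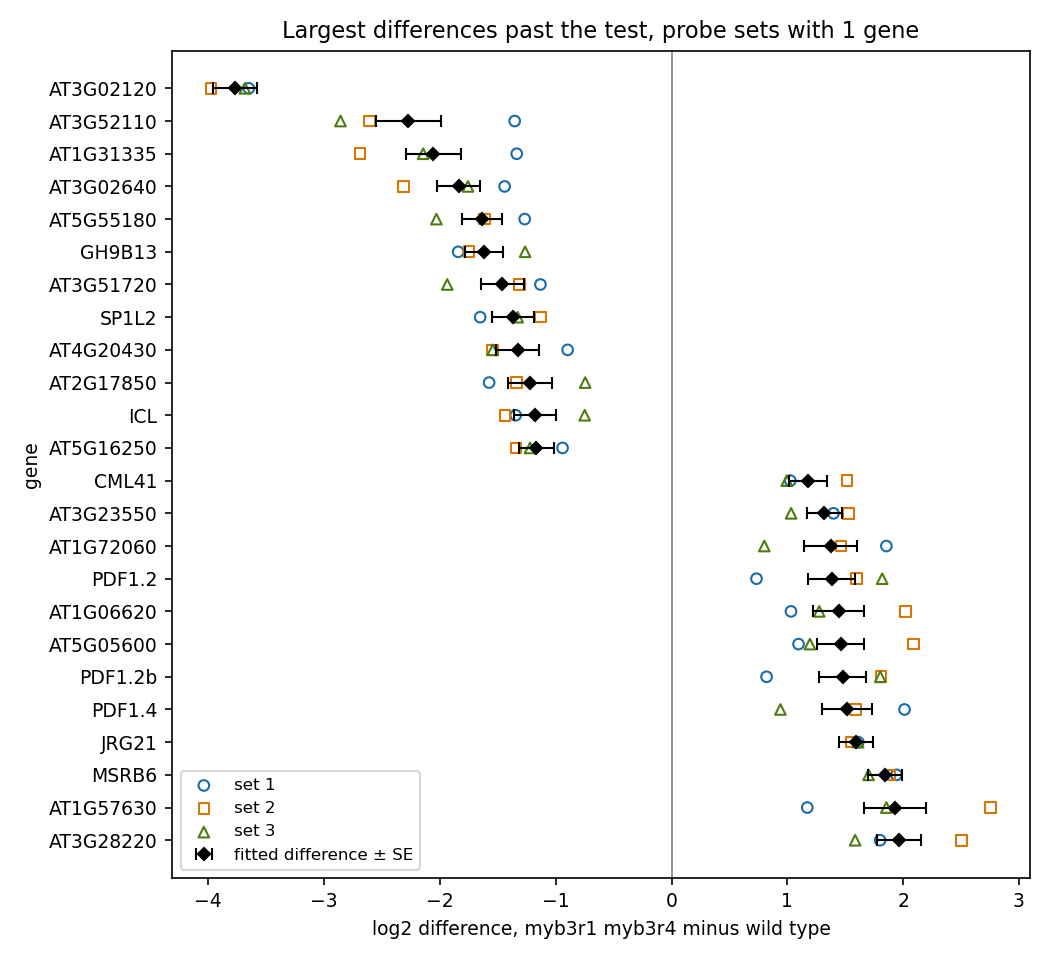
Log2 difference (double mutant minus wild type, x axis) of the 12 genes with the largest fall and the 12 with the largest rise among probe sets of exactly 1 gene past adjusted p 0.05 (y axis); open symbols are the differences in sets 1, 2 and 3, and black diamonds with bars are the fitted difference ± SE. All 24 genes lay on the same side of 0 in all 3 sets, which was a condition of their choice, and AT3G02120, at -3.77, stood furthest from 0.

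Most tested genes of jasmonate response and of defence were higher in the mutant. In the list of jasmonate and defensin genes, 6 of 7 tested members were higher in the mutant and the list median was 0.71. PDF1.4 rose by 1.51 (SE 0.22, adjusted p = 0.0320), and PDF1.2b and PDF1.2 rose by 1.48 and 1.38 from already high levels of 5.32 and 5.07. PDF1.2 and PDF1.2b are near-identical in sequence, so their probe sets may read each other's transcripts and their separate values are uncertain. Over all genes 3 members passed and, adjusted over the list alone, 4 did, the added one being OPCL1, an enzyme gene of jasmonate synthesis (0.71, SE 0.25). Set 2 carried most of the OPCL1 value, with differences of 0.23, 1.58 and 0.31 in sets 1 to 3. Camera with a preset correlation called the list higher (adjusted p = 0.00366), but not with the estimated correlation of 0.39 (adjusted p = 0.488 with an estimated correlation). The list median was 0.23, 1.58 and 0.48 in sets 1 to 3, where the mutant minus wild-type difference of the 3' minus 5' signal of control genes was 0.44, -1.12 and -0.78. It was 0.27 without set 2 (adjusted p = 0.00365) and 0.39 with that control difference as a covariate (adjusted p = 0.00154), an alternative added after seeing the data.

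In the defence list 11 of 13 tested members were higher, with a median of 0.36. WRKY53, a transcription factor gene of senescence and defence, rose by 0.94 (SE 0.16, adjusted p = 0.0462), with differences of 0.98, 1.06 and 0.76 in the 3 sets. WRKY6 had a difference of 0.68 (SE 0.16) and passed only when adjusted over the list alone, where 2 members passed. The list was called higher by camera (adjusted p = 0.00460; adjusted p = 0.464 with an estimated correlation). Its medians in the 3 sets were 0.34, 0.44 and 0.35. The call of the defence list was not made among the brightest 40% of probe sets (median 0.25, adjusted p = 0.305). That filter leaves out the dimmer members of the list.

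Neither tested list of mitosis and cytokinesis genes was called, while the list of kinesins was called lower. Many of the usual mitotic genes had no named probe set. Of 37 spindle, checkpoint and cytokinesis genes listed 10 had one and 7 were tested. Of 20 mitotic cyclin and CDKB genes 0 had one, and 31 of the 72 called probe sets carried no gene name. The lists below therefore do not show how the untested genes behaved. In the list of spindle, checkpoint and cytokinesis genes 4 of 7 tested members were lower and 3 higher, the median was -0.053 and the mean -0.017 (camera adjusted p = 0.646). None of its members passed, including KEU, a cytokinesis gene, at 0.19 (SE 0.18), and AUR1, a mitotic Aurora kinase gene, at 0.28 (SE 0.18). In the list of kinetochore, condensin and spindle proteins 7 of 9 members were lower, with a median of -0.17 (camera adjusted p = 0.0750). Its bright members 3xHMG-box2 and BUB3.1 differed by 0.19 and 0.0054. Of 15 kinesin motor genes 12 were lower, with a median of -0.14 and 0 past the test in limma by either adjustment, KINESIN-13A at -0.18 (SE 0.15) and AT3G16060 at 0.072 (SE 0.15). Camera called the kinesins lower as a list (adjusted p = 0.00483), but not with an estimated correlation (adjusted p = 0.488). Nor did it among the brightest 40% of probe sets (median -0.16, adjusted p = 0.225). The camera call held without the block (adjusted p = 0.00968) and with quantile normalization (adjusted p = 0.0393). It also held without set 1, set 2 or set 3 (adjusted p = 0.0121, 0.0442 and 0.0282). Signs of RNA quality moved with these lists: the mean 3' minus 5' signal of control genes was 1.07, 3.04 and 3.22 in the wild-type arrays of sets 1 to 3, and the mutant minus wild-type difference of this signal was 0.44, -1.12 and -0.78. The spindle, checkpoint and cytokinesis median was 0.50, -0.53 and -0.12 in the same 3 sets, and the kinesin median -0.012, -0.41 and -0.10. With the control difference as a covariate, added after seeing the data, the median of the first list was 0.22 and that of the kinesins -0.079, and without set 1 the kinesin median was -0.30.

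**Figure D2:**
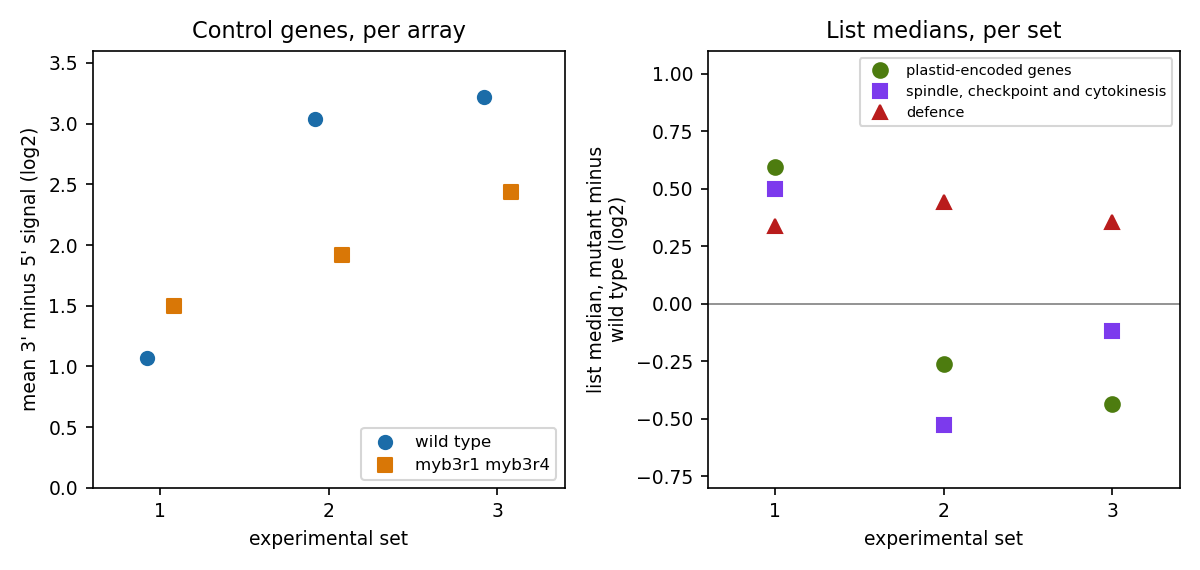
Left, mean 3' minus 5' log2 signal of control genes for each array, by experimental set (x axis) and genotype. Right, median log2 difference (double mutant minus wild type) of 3 gene lists in each set: the plastid-encoded and the spindle, checkpoint and cytokinesis medians were above 0 in set 1 and below 0 in sets 2 and 3, and the defence medians lay between 0.34 and 0.44.

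Core histone genes, whose transcripts accumulate in S phase, were higher in the mutant at all 16 tested probe sets: 6 of H2B, 5 of H3.1 and 5 of H4 genes. The median was 0.24, and no probe set passed by itself in limma, over all genes or over the list alone. HTB4 had a level of 4.33 ± 0.27 in wild type and 4.78 ± 0.40 in the mutant (SD, n = 3 each). Probe sets of the H3.1 and H4 genes match several near-identical genes and are not independent of each other. Camera called the list higher (adjusted p = 0.00460; adjusted p = 0.464 with an estimated correlation), and with quantile normalization the median was 0.11 and the list was not called (adjusted p = 0.106), nor was it without set 1 (adjusted p = 0.0598). Among 6 genes of replication and chromatin assembly 3 were lower and 3 higher, with a median of -6.95e-04 (camera adjusted p = 0.449). In the same list ASF1B, a histone chaperone gene, differed by -0.33 (SE 0.17), PRL, a replicative helicase gene, by -0.064 (SE 0.14), and ICU2, a DNA polymerase gene, by -0.23 (SE 0.17). All 3 tested DNA repair genes were lower, with RAD4 at -0.22 and ATLIG4 at -0.22, but the list was not called (camera adjusted p = 0.142). Its median was 0.080, -0.42 and -0.24 in sets 1 to 3, where the 3' minus 5' control difference was 0.44, -1.12 and -0.78.

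Nuclear genes of chloroplast proteins were higher in the mutant for all 23 tested members, with a median of 0.17 and no member past the test in limma by either adjustment. RCA, which encodes Rubisco activase, had a level of 6.46 ± 0.12 in wild type and 6.82 ± 0.15 in the mutant (SD, n = 3 each), and PSAE-1, of photosystem I, differed by 0.20 (SE 0.12). Camera called this list higher (adjusted p = 0.00460; adjusted p = 0.464 with an estimated correlation), and with quantile normalization its median was 0.026 and the call was lost (adjusted p = 0.387). It was also lost without set 3 (median 0.17, adjusted p = 0.149). In the smaller photosynthesis list 3 of 3 tested genes were higher with a median of 0.33 (camera adjusted p = 0.0750), which was 0.10 with quantile normalization. RCA and PRK, which encodes phosphoribulokinase, passed there when adjusted over the list alone, at 0.36 (SE 0.12) and 0.33 (SE 0.13).

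Plastid-encoded genes were spread on both sides of 0, 44 lower and 32 higher among 76, with a median of -0.058. None passed over all genes. psbB, of the photosystem II core, differed by -0.81 (SE 0.15) and passed when adjusted over the list alone, and the bright genes atpB and psbM differed by 0.019 and 0.22. Their median was 0.59 in set 1, -0.26 in set 2 and -0.44 in set 3, where the mutant minus wild-type difference of the 3' minus 5' control signal was 0.44, -1.12 and -0.78. Camera with the preset correlation called the list lower (adjusted p = 0.00483; adjusted p = 0.829 with an estimated correlation), the estimate being 0.64. The median was -0.34 without set 1 (adjusted p = 1.81e-17), 0.082 without set 2 and 0.13 without set 3, and -0.21 with quantile normalization (adjusted p = 5.83e-05). Without the block the list was not called (adjusted p = 0.0688), and with the control difference as a covariate, added after seeing the data, it was 0.28 and the list was called higher (adjusted p = 3.53e-04).

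Of the cold, drought and ABA response genes 3 probe sets were tested, 2 lower and 1 higher. The list median was -0.63, and COR15A, a gene induced by cold, differed by -0.70 (SE 0.25), one of 2 probe sets that passed when adjusted over the list alone, where 0 passed over all genes. The COR15A differences in sets 1 to 3 were uneven, at -1.43, -0.026 and -0.66. Camera called this list lower (adjusted p = 0.0474), but not with an estimated correlation (adjusted p = 0.488) or without the block (adjusted p = 0.0688). Nor was it called with quantile normalization (adjusted p = 0.0611), with the median division undone (adjusted p = 0.0713), without set 1 (median -0.34, adjusted p = 0.112) or without set 3 (adjusted p = 0.168). Camera did call it without set 2 (median -0.57, adjusted p = 4.7e-04). With the 3' minus 5' control difference as a covariate, added after seeing the data, it was called too (median -0.45, adjusted p = 0.00157). The overlapping list of 8 cold and dehydration genes had a median of -0.11 with 6 members lower (camera adjusted p = 0.0750), where COR15B passed over the list alone at -0.58 (SE 0.15), DI21 differed by -0.51 (SE 0.28) and COR47 by 0.087 (SE 0.24). Set 2 carried the DI21 value, with differences of 0.37, -1.45 and -0.45 in sets 1 to 3.

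**Figure D3:**
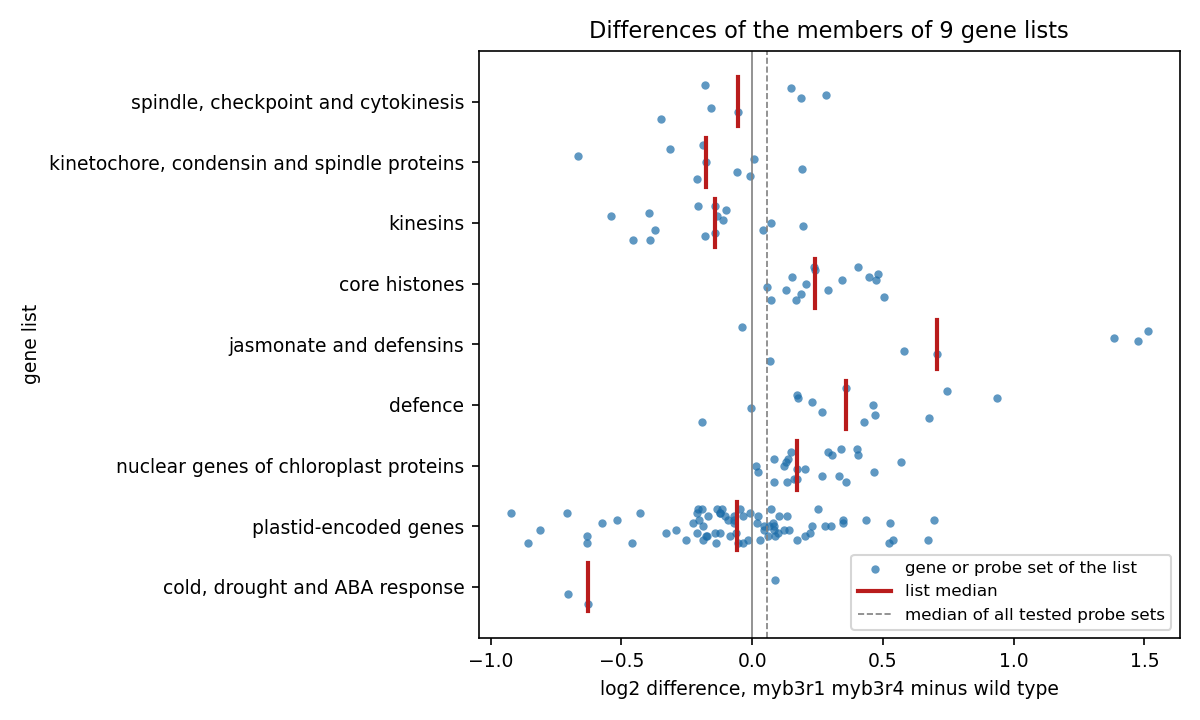
Log2 difference (double mutant minus wild type, x axis) of the tested members of 9 gene lists (y axis); each point is a gene or probe set, red bars are list medians and the dashed line is the median of all tested probe sets, 0.058. All core histone probe sets and all nuclear genes of chloroplast proteins lay above 0, by medians of 0.24 and 0.17, and the plastid-encoded genes lay on both sides.

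No other tested list was called. Of 20 glutathione and glycosyl transferase genes 16 were higher, with a median of 0.30 (camera adjusted p = 0.0750). The median was 0.067, 0.56 and 0.23 in sets 1 to 3, where the 3' minus 5' control difference was 0.44, -1.12 and -0.78. It was 0.16 with quantile normalization and 0.18 with the median division undone. The bright members GSTU20 and GSTL3 of this list differed by 0.71 (SE 0.17) and 0.28 (SE 0.21). Of 6 root-enriched genes 5 were higher, with a median of 0.33 (camera adjusted p = 0.0750). In sets 1 to 3, with the same control differences, this median was -0.11, 0.80 and 0.34, and it was 0.20 with quantile normalization. JAL33, a jacalin-like lectin gene, passed there when adjusted over the list alone at 1.03 (SE 0.21), while the beta-glucosidase gene PYK10 differed by 0.33 (SE 0.15), as did NAI2, of the same endoplasmic reticulum bodies, by 0.41 (SE 0.16). The root and root hair list held 3 tested genes with a median of 0.33 (camera adjusted p = 0.630), AT5G17820 at -0.14 (SE 0.27). Tubulin genes (7 tested, median 0.089), expansin and XTH genes (15 tested, median 0.10) and auxin genes (5 tested, median 0.11) had camera adjusted p values of 0.945, 0.928 and 0.928. The median of the tubulins was below 0 with quantile normalization, at -0.070, and those of all 3 lists were below 0 with the median division undone. In these lists TUA6 differed by 0.089, TUB6 by -0.17, EXGT-A3 by 0.54 (SE 0.15), EXPA4 by -0.068, IAA18 by 0.29 and GH3.3 by 0.50 (SE 0.20), and none passed.

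Lists with fewer than 3 tested members were left as single values, none of which passed except PDF1.2. SIM, an inhibitor gene of the cell cycle, differed by 0.23 (SE 0.18), the clock gene GI by -0.47 (SE 0.25), the cytokinin response regulator gene RR16 by -0.034 (SE 0.21) and the organ polarity gene YAB3 by 0.070 (SE 0.16). Set 1 carried the GI value, with differences of -1.33, 0.091 and -0.17 in sets 1 to 3. The stomatal genes STOMAGEN and FMA differed by -0.11 (SE 0.24) and 0.14 (SE 0.20), and the members of the pollen and seed list SCPL49 and PLIM2b by 0.12 (SE 0.14) and -0.26 (SE 0.17). MYB3R1, MYB3R4, the other MYB3R genes, the mitotic cyclins and B-type cyclin-dependent kinases, KN, HIK, EDE1 and CDC20.1 were not analysed here, because no probe set was paired with any of these names, so the genotype labels were not checked against the targeted transcripts.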

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

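All 72 probe sets past the threshold kept their direction under every alternative that tested them. For most alternatives this follows by construction, since all 72 moved the same way in all 3 sets. Quantile normalization and the control difference as a covariate could have changed a direction and changed none. The offset, the fit without a mean-variance trend, robust empirical Bayes and array median centring kept the counts within 1.5 times. Centring left the 72, since the deposited columns already have a median of 0. With a 2-fold minimum 61 remained, and the mean of a gene's probe sets changed no list call. MAS5 signals of dim probe sets limit the test: 14 probe sets passed without a filter (7 lower, 7 higher) and 43 among the brightest 40% (11 lower, 32 higher), where by construction other probe sets were tested. With an adjusted p of 0.10, which by construction admits more, 251 passed (57 lower, 194 higher). Without the replicate block 1 passed (1 lower, 0 higher), and the cold, drought and ABA list (-0.63, adjusted p = 0.0688) and the plastid-encoded list (-0.058, adjusted p = 0.0688) were not called.

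With quantile normalization 3 list calls were lost: cold, drought and ABA (-0.72), core histones (0.11) and nuclear genes of chloroplast proteins (0.026). The signs reversed for an H4 probe set (-0.053), BUB3.1 (-0.047), TUA6 (-0.16), COR47 (-0.063), atpB (-0.043) and SCPL49 (-0.047), none of them past the threshold. The spindle, checkpoint and cytokinesis median was 0.020 without a filter and 0.066 among the brightest 40%, where the kinesins (-0.16, adjusted p = 0.225) and defence (0.25, adjusted p = 0.305) were not called. With an estimated correlation no list was called: cold, drought and ABA (-0.63), core histones (0.24), kinesins (-0.14), nuclear genes of chloroplast proteins (0.17), defence (0.36), jasmonate and defensins (0.71) and plastid-encoded genes (-0.058). This form of camera used only the 2 residual degrees of freedom. For core histones, defence and nuclear genes of chloroplast proteins the estimate lay below the preset correlation.

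The next alternatives were chosen after seeing the data. With the median division undone 33 probe sets were lower, cold, drought and ABA (-0.75, adjusted p = 0.0713) was not called, and YAB3 (-0.053), AT3G16060 (-0.051), BUB3.1 (-0.12), TUA6 (-0.035), COR47 (-0.037) and atpB (-0.10) reversed, which follows from the shift of all values by -0.124. With the 3' minus 5' control difference as a covariate, which leaves 1 residual degree of freedom, 194 passed (52 lower, 142 higher). The spindle, checkpoint and cytokinesis median (0.22), the plastid-encoded median (0.28), RR16 (0.27), KEU (-0.0039), STOMAGEN (0.31), FMA (-0.032), AT3G16060 (-0.036), RAD4 (0.037), COR47 (-0.20) and GSTL3 (-0.064) reversed. The jasmonate and defensins median was 0.39 and the kinesin median -0.079, and both lists were called.

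Leaving out 1 set at a time, the counts ranged from 107 to 1107 (lower 25 to 189, higher 82 to 918). List medians ranged from -0.57 to -0.34 for cold, drought and ABA, 0.27 to 0.30 for core histones, 0.17 to 0.24 for nuclear genes of chloroplast proteins, -0.30 to 0.16 for spindle, checkpoint and cytokinesis, -0.34 to 0.13 for plastid-encoded genes, 0.27 to 0.94 for jasmonate and defensins, 0.35 to 0.41 for defence and -0.30 to -0.13 for kinesins. Genes that reversed ranged as follows: an H4 probe set -0.043 to 0.22, RR16 -0.35 to 0.19, YAB3 -0.088 to 0.21, AT5G17820 -0.59 to 0.23, KEU -0.055 to 0.33, STOMAGEN -0.50 to 0.18, BUB3.1 -0.024 to 0.046, EXPA4 -0.21 to 0.046, COR47 -0.33 to 0.30, atpB -0.14 to 0.11 and psbM -0.059 to 0.48. Where construction does not show it, the cause was not tested.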

Other observations

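Further genes past the test lie outside the naming rule and were chosen after their values were seen. The jacalin-related lectin genes AT1G52000 and AT1G52100 rose by 1.09 (SE 0.16, adjusted p = 0.0320) and 1.02 (SE 0.16, adjusted p = 0.0377). AT1G14120, an oxygenase gene, rose by 1.15 (SE 0.17) and AT2G25200 by 1.18 (SE 0.20, adjusted p = 0.0456). Among the lower genes AT5G64550 fell by 0.89 (adjusted p = 0.0447).

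The tests of the first pattern and of the count were written before their results were seen, but the tests of the first pattern with the covariate and without histones, and the paired test of scaling, were added afterwards. Genes of mitosis and cytokinesis, 16 from both lists, had a median of -0.11 (95% interval -0.19 to 0.0054), 11 of them lower, so the pattern's own interval includes 0. Fewer dividing cells in the mutant seedlings, the biological explanation, would lower S phase genes about as much, and the S phase median minus the mitotic median was 0.305 (interval 0.13 to 0.44) and 0.19 with quantile normalization (interval 0.055 to 0.36), which argues against it. It cannot be told apart all the same: the difference was 0.21 with the control difference as a covariate (interval -0.075 to 0.39), 16 of the 22 S phase probe sets are of core histone genes, many near-identical, and the 6 other genes gave 0.11 (interval -0.21 to 0.30). Quantile normalization, which took the median of nuclear genes of chloroplast proteins from 0.17 to 0.026, left the mitotic median at -0.125. The paired shift was -0.017 (interval -0.050 to 0.0024), which argues against scaling of the arrays as the whole source of this median. Taken relative to the median of all tested probe sets, the values shrank under quantile normalization. The spindle, checkpoint and cytokinesis median went from -0.11 to -0.065, and that of kinetochore, condensin and spindle proteins from -0.23 to -0.16. A part from scaling therefore stays open. The undone division took the mitotic median to -0.23, but it adds the same -0.124 to every gene and so decides nothing here. Noise of dim probe sets cannot be told apart, with a median of 0.19 in 5 bright members (interval -0.16 to 0.28). Nor can 3' bias of the RNA, with a median of 0.16 in set 1 (interval -0.11 to 0.49). With the control difference as a covariate the mitotic median was 0.078, above 0.

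The count of probe sets past the threshold was 1107 without set 1 and 72 with all 3 sets. Of 1035 probe sets past it only without set 1, 64.9% moved the same way in set 1 (interval 61.9 to 67.8%). This argues against chance agreement of sets 2 and 3 as the whole cause. Their median difference in set 1, signed by the other sets, was 0.11 (interval 0.089 to 0.13) beside 0.79 in sets 2 and 3. This argues against 3' bias reversing in set 1 as the whole cause, and a mixture with it stays open. Both intervals treat probe sets as independent, while all their set 1 differences come from 1 pair of arrays. The intervals are therefore too narrow, and neither explanation is excluded. Those called only without set 2 or only without set 3 moved the same way in the left-out set in 86.5% and 92.2%. No biological explanation was tested for this pattern.

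There are 10 splits of the 6 arrays into 3 and 3, too few for a share under 0.05: the real split gave 72 and the highest other gave 121, and 3 splits including the real one gave at least 72. The 3 other splits that part all 3 sets, the ones comparable with the real split, gave 0. The 121 stands for both splits that part set 2 only, where the blocked fit takes its difference from the wild-type and mutant arrays of that set alone, so these are the same fit of a genotype difference and not an exchange of genotypes.

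The tests of the defence and jasmonate pattern were written after its values were seen, and PDF1.2 and PDF1.2b count once in them. The 13 defence genes had a median of 0.36 (interval 0.17 to 0.47). With the control difference as a covariate it was 0.36 (interval 0.18 to 0.48), a paired shift of 0.0042 (interval -0.091 to 0.12). This argues against 3' bias of the RNA as the whole cause. With quantile normalization the median was 0.33 (interval 0.10 to 0.47), a paired shift of -0.027 (interval -0.17 to 8.00e-04). This argues against scaling as the whole cause. The undone division gave 0.24, but it adds the same -0.124 to every gene and so decides nothing here. Noise of dim probe sets cannot be told apart for the 13 defence genes, since only 2 are bright (median 0.22). The list was not called among the brightest 40% of probe sets, where its dimmer members were not tested. The 6 jasmonate and defensin genes had a median of 0.64 (interval 0.016 to 1.47). With quantile normalization it was 0.60, a paired shift of -0.040 (interval -0.20 to -0.0068). Most of the median was kept, which argues against scaling as the whole cause for these 6 genes. The interval of the median itself then included 0 (-0.017 to 1.36), so the rise is uncertain under that scaling. The undone division gave 0.52 (interval -0.11 to 1.35), again by the same -0.124, which decides nothing. For these genes 3' bias cannot be told apart, with a median of 0.29 with the covariate (interval -0.056 to 1.42). That is a paired shift of -0.35 (interval -0.38 to -0.054), by which most of the median was lost. Noise of dim probe sets is no cause for the bright PDF1.2 and PDF1.2b, but for the list it cannot be told apart: the call held among the brightest 40% of probe sets (median 0.71, adjusted p = 0.0331), yet with both counted once 3 of 4 genes left there were higher, with a median of 0.39 (interval -0.038 to 1.43), and 2 above the median level had 1.07. A part of 3' bias in either list and growth or handling that differs between the genotypes, which was not tested, stay open.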
